A study of Homo sapiens with 21 samples.

How the data were processed

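THP1 cells, a human acute myeloid leukemia line that grows as monocyte-like cells, were profiled by RNA sequencing after knockdown of IRF2BP2 with short hairpin RNAs in a lentiviral vector, or after CRISPR editing of ATF7 or JDP2 with isolation of single-cell clones, per the labels' protocols. Total RNA was extracted on columns with DNase digestion, and messenger RNA libraries were prepared for Illumina sequencing, per the labels' protocols. The submitters' processing notes name hg38, featureCounts and DESeq2, without versions. The aligner, the gene annotation and the strand setting are not given in the sources used here, so reads shared between near-identical genes, overlapping genes or antisense genes could not be assigned further.

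The authors deposited a table of DESeq2-normalized gene values, which is a signal per gene and library (read count divided by 1 size factor per library). It has 20423 genes and 19 libraries. In each library the values were whole multiples of 1 step within a tolerance of 0.01, for 100 percent of the 388037 values, so read counts were recovered by dividing by that step. The authors also deposited 3 comparison tables with the base mean as a signal, a log2 fold change and its standard error, a Wald score, and a p-value with its adjusted p-value. In the authors' deposited tables the base mean equalled the mean over all 19 libraries, and the log2 fold change for the knockdown followed the knockdown libraries over all 5 control libraries, with a median absolute difference of 0.0293, against 0.125 for shRNA control alone. The Wald score has the opposite sign of the log2 fold change in 100 percent of genes in all 3 deposited tables, so directions were taken from the fold change. All 19 columns of the normalized table were used.

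The labels describe 21 libraries, of which 2 are marked as low quality (shRNA control replicate 2 and wild type replicate 1). Both were not analysed here. Recovered reads in genes ranged from 28.7 to 60.2 M (mega) reads per library, and 14263 to 19046 genes had at least 1 read. The highest correlation between any pair of libraries was 0.985 on log2 values. Libraries of 1 hairpin, clone or control group differed by more than sampling noise, with a chi-square per gene of at least 93.2, as separate preparations from 1 culture would too, and each column was treated as a separate sample. The labels do not say whether replicates came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

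Values were transformed as log2(normalized count + 1), and fold changes are on that scale, which understates the change of low genes. Genes with a mean normalized count of at least 10 over the libraries of a fit were tested with limma moderated statistics (empirical Bayes with a trend), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The knockdown fit held shRNA control and both hairpins, which formed 1 group. The knockout fit held the knockout control and all ATF7 and JDP2 clones, with the clones of a knockout as 1 group. Hairpins and clones were compared in fits with a group for each. The knockdown and knockout effects were compared by an interaction contrast in 1 fit of both arms. Lists of genes fixed before the data were examined were tested with limma camera at a preset inter-gene correlation of 0.01, with adjustment over 29 lists within a comparison, and again with an estimated correlation and with fry. ATF7 and JDP2 knockouts share their 2 control libraries, so correlations and overlaps between them were set beside 100 simulated draws of unchanged groups, and shared calls beside 20 fitted draws.

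The genes named were chosen by a rule fixed before the data were examined. It takes the targeted genes and their partners where called, the 10 called genes with the largest rise and the 10 with the largest fall that have a gene symbol, a mean of at least 50 normalized counts in either group and the same sign in each hairpin or clone, and up to 4 called members of each list by lowest p, or the 2 members with the highest level where none was called. For differences between hairpins or clones it takes the 5 largest rises and falls, and for shared genes the 5 with the largest smaller change. Of the genes this rule takes, 2 are not reported here.

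Same-numbered libraries were checked for pairing from the correlation of their deviations from the group means. By that check the numbers did not pair the libraries throughout, and the result is given with the alternatives. Counts were simulated with the means, library sizes and spread of a fit, independently between genes. Changed genes were drawn from those with a mean of at least 50, so the shares do not cover lower genes. For the knockdown (12560 genes), limma called 98 percent of genes changed by 4 on the log2 scale, 72 percent at 2 and 8 percent at 1, and 0.113 percent of unchanged genes. For the ATF7 knockout (12918 genes) these shares were 98, 82, 6 and 0.0865 percent, and for the JDP2 knockout (12890 genes) 96, 76, 4 and 0.0788 percent. A planted list was called and 0 of 28 random lists were. The simulated genes varied independently of each other. This check therefore does not tell how often an unchanged list of correlated genes would be called.

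Alternatives covered the pseudocount (0.5 and 5), the filter, the scaling, edgeR and DESeq2 on recovered reads, the handling of hairpins and clones, a replicate block, the control libraries, array weights, the authors' deposited calls, and leaving out each library. After the data were seen, a removal of each library's GC trend in 50 bins, other control sets for the knockouts, other scalings for the gene lists (equal totals and quantile normalization), each knockout against a different knockout control library, and the exclusion of libraries with over 20 percent of genes more than 2-fold from the median of all libraries were added. Gene symbols were matched to GENCODE release 29 on GRCh38, the assembly that hg38 names, for 20230 genes, and positions are from that annotation. Transcript GC content and length were found for 19482 genes. Analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.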

Results

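Gene expression was measured by RNA sequencing in THP1 cells, a monocytic acute myeloid leukemia line, in which IRF2BP2, ATF7 or JDP2 had been targeted. IRF2BP2 is a transcriptional cofactor, and ATF7 and JDP2 are basic leucine zipper transcription factors that can form a heterodimer. The knockdown arm held 3 libraries of each of 2 IRF2BP2 hairpins and 2 libraries of an shRNA control. The knockout arm held 2 libraries of each of 2 single-cell clones for ATF7 and for JDP2, and 2 libraries of a knockout control. There was also 1 wild-type library. The 19 libraries held 28.7 to 60.2 M (mega) reads in genes, which were read as normalized counts. Over 20 percent of genes lay more than 2-fold from the median of all libraries in 3 libraries, namely IRF2BP2 shRNA 1 replicate 3 (45.3 percent), IRF2BP2 shRNA 2 replicate 3 (21.8 percent) and JDP2 knockout clone 1 replicate 2 (34.6 percent).

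The targeted genes were examined first in every library. IRF2BP2 lies on chromosome 1 from 234604269 to 234609525 on the minus strand (GRCh38). Its normalized count was 16973 and 18382 in the shRNA control libraries, 9456, 11109.7 and 9802 in IRF2BP2 shRNA 1, and 12587, 16649 and 25651 in the libraries labelled IRF2BP2 shRNA 2. Means were 17677 ± 997 (SD, n = 2) in shRNA control, 10122 ± 872 (SD, n = 3) in shRNA 1 and 18296 ± 6686 (SD, n = 3) in shRNA 2. Over both hairpins the log2 change of IRF2BP2 was -0.41 ± 0.42 (SE), with a limma adjusted p of 0.715, and it was lower than the control mean in 5 of 6 libraries. The library labelled IRF2BP2 shRNA 2 replicate 3 had more IRF2BP2 message than either shRNA control library, against its label, so every direction given for the knockdown includes a library whose message level goes against its label. In wild type IRF2BP2 stood at 18154, in the knockout control libraries at 21364 and 14859, in the ATF7 knockout libraries between 17579.8 and 27597, and in the JDP2 knockout libraries between 17839.8 and 27436.

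ATF7 lies on chromosome 12 from 53507856 to 53626410 on the minus strand. Its normalized count was 299.9 and 537 in the knockout control libraries, 645 and 511 in ATF7 knockout clone 1, and 617 and 363 in ATF7 knockout clone 2. The ATF7 log2 change was 0.38 ± 0.36 (SE), with a limma adjusted p of 0.845. In the other groups ATF7 stood at 210.0 and 499 (shRNA control), 387 (wild type), 299, 168, 307 and 306 (JDP2 knockout), 398, 608 and 1337 (shRNA 1), and 526, 438 and 495 (shRNA 2). JDP2 lies on chromosome 14 from 75427716 to 75474111 on the plus strand. Its normalized count was 5085 and 3438 in the knockout control libraries, 3158 and 5693 in JDP2 knockout clone 1, and 4652 and 5368 in JDP2 knockout clone 2. The JDP2 log2 change was 0.14 ± 0.35 (SE), with a limma adjusted p of 0.882. In the other groups JDP2 stood at 5004 and 2966 (shRNA control), 3560.4 (wild type), 4817, 5042, 2636 and 5447 (ATF7 knockout), 3437, 3201 and 1104 (shRNA 1), and 3812, 3646 and 6394 (shRNA 2). Neither change passed the test, and each turned without 1 knockout control library, that of ATF7 to -0.044 without replicate 1 and that of JDP2 to -0.14 without replicate 2. A CRISPR edit can end the protein and leave the message, so these levels do not check the knockout labels.

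**Figure D1:**
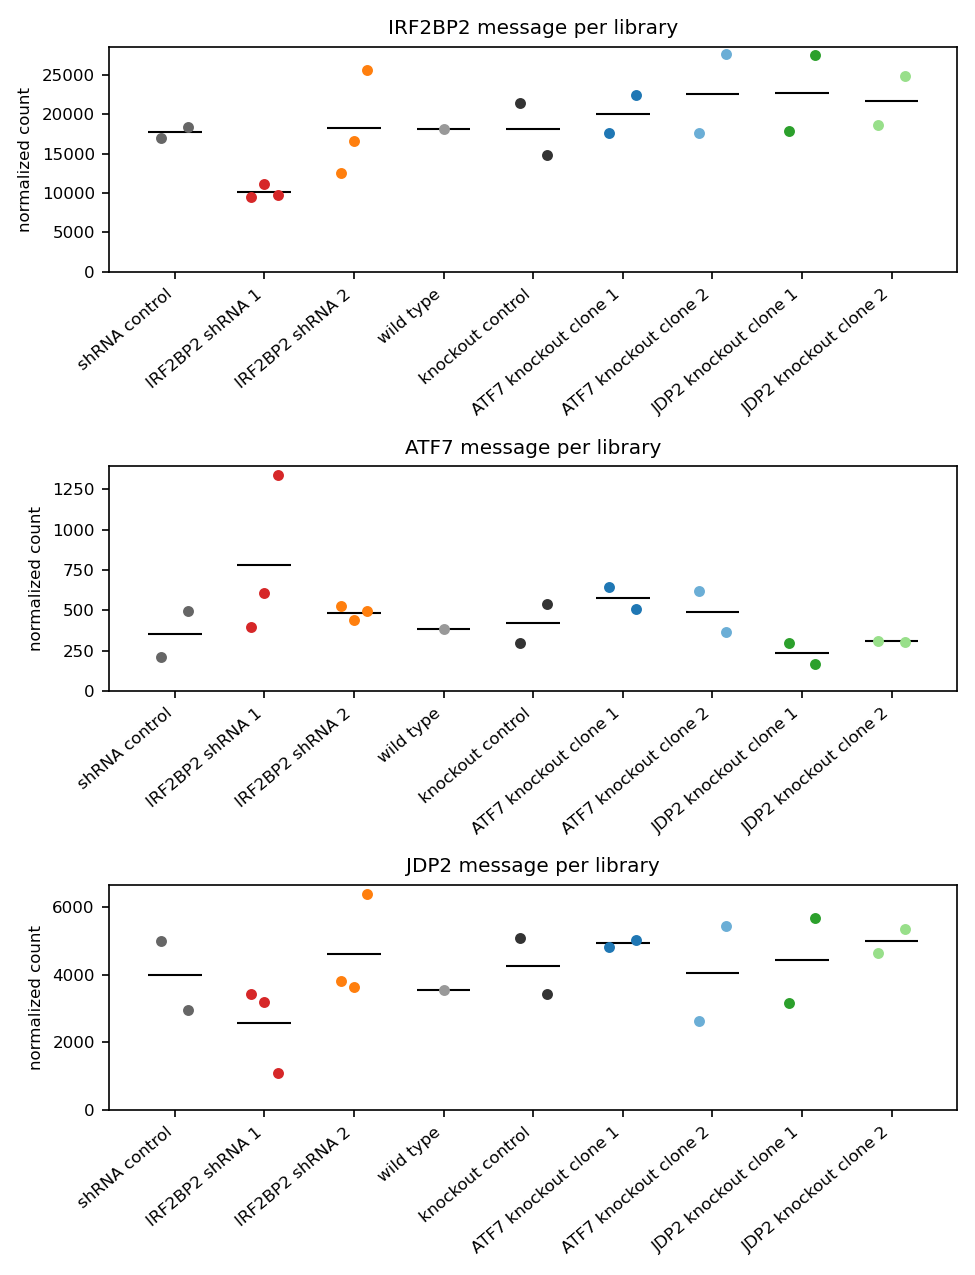
Normalized counts of IRF2BP2, ATF7 and JDP2 in each library, by group. Points are libraries and horizontal bars are group means. IRF2BP2 stood between 9456 and 11109.7 in the shRNA 1 libraries and between 12587 and 25651 in those labelled shRNA 2.

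The comparison of the IRF2BP2 knockdown with shRNA control asked which messages depend on IRF2BP2, named in the study's title as a brake on inflammatory activity. In the libraries labelled as knockdown, 15 of 37 monocyte and macrophage differentiation genes and 12 of 41 interferon-stimulated genes rose, and both lists were called upward by camera, but not with an estimated correlation (adjusted p = 0.218 and adjusted p = 0.295). GPR34, a G protein-coupled receptor of myeloid cells, rose from 5.74 ± 2.49 (SD, n = 2) to 740.2 ± 619 normalized counts (SD, n = 6), a log2 change of 6.44 ± 0.67 (SE) with a limma adjusted p of 0.00268. OAS1, an interferon-induced sensor of double-stranded RNA, rose from 60.8 ± 21.3 to 2632 ± 2113, a log2 change of 4.99 ± 0.75 (SE, adjusted p = 0.00562). CCR1, a chemokine receptor of monocytes, rose from 134 ± 17.5 to 2035 ± 1117, a log2 change of 3.74 ± 0.48 (SE, adjusted p = 0.00349). TERT, the catalytic subunit of telomerase, fell from 1007 ± 7.33 to 165 ± 68.2, a log2 change of -2.74 ± 0.46 (SE, adjusted p = 0.0101). Each of these moved the same way in 6 of 6 libraries.

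**Figure D2:**
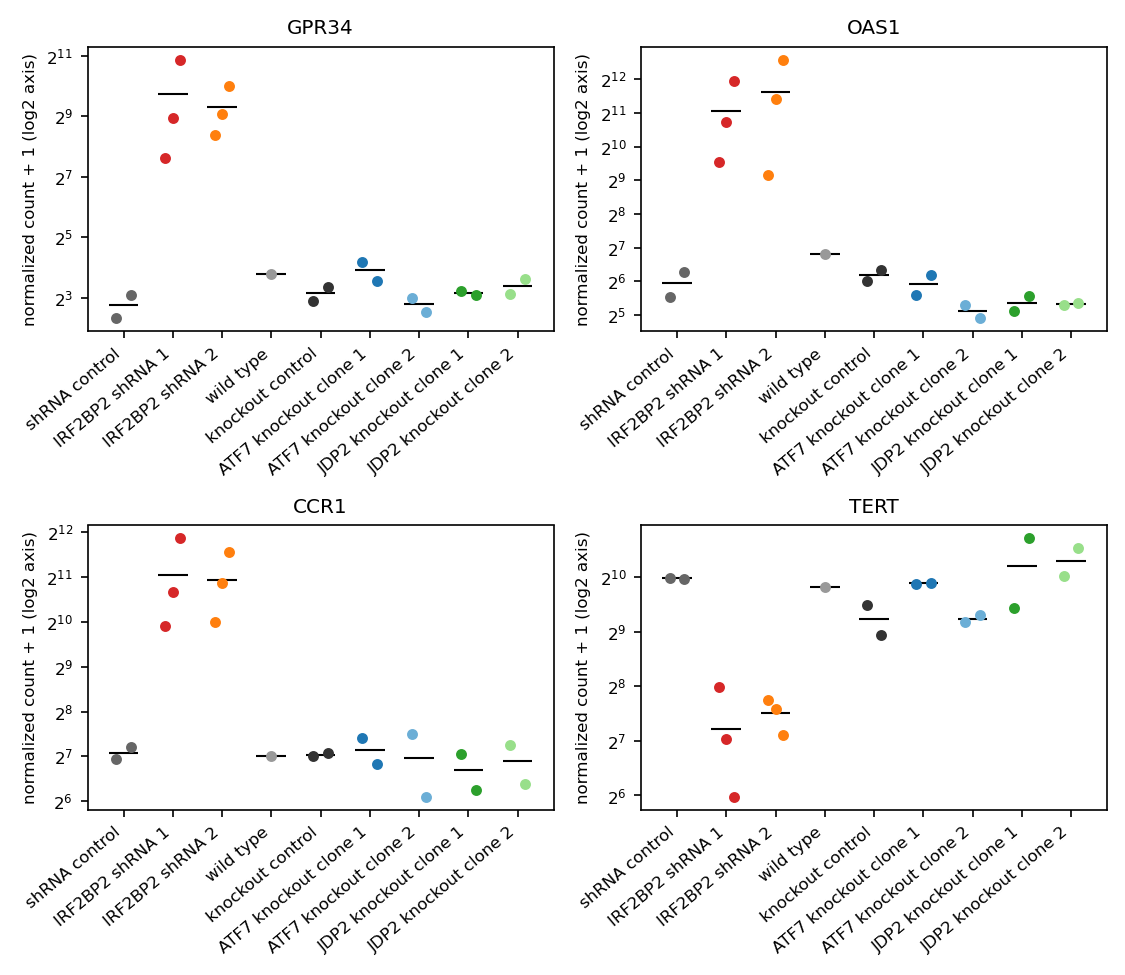
Normalized counts plus 1, on a log2 axis, of GPR34, OAS1, CCR1 and TERT in each library, by group. Points are libraries and horizontal bars are group means of the counts. GPR34 lay between 194 and 1869 in the 6 knockdown libraries and between 3.98 and 17.2 in the other libraries.

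The other genes with the largest rises included cell surface receptors of myeloid cells. AQP9, an aquaglyceroporin, had 0 reads in both shRNA control libraries and 246 ± 260 normalized counts (SD, n = 6) in the knockdown, at least 82.5-fold higher when each control library is set to 3 reads. On the same floor RNASE1, a secreted ribonuclease, was at least 31.1-fold higher and SIGLEC9, a sialic acid-binding receptor, at least 25.9-fold higher. The bounds of AQP9 and SIGLEC9 are raised by 1 knockdown library each, at 741 (next highest 256) and 226 (next highest 70.4). SIGLEC9 also stood at 12.7 in wild type, at 42.4 and 20.4 in the knockout control and at 730 and 316 in ATF7 knockout clone 1. The authors' deposited table, which used all 5 controls, did not call it in the knockdown (log2 change 0.72 ± 0.46, SE). Its knockdown mean was 77.4, so that deposited change is smaller than these counts give and is not comparable in size with the limma changes. Limma with wild type and knockout control added to the control kept all 228 calls, SIGLEC9 among them. FPR1, the formyl peptide receptor, had a log2 change of 6.39 ± 0.80 (SE), CLEC7A, the beta-glucan receptor dectin-1, of 6.34 ± 1.07 (SE), SLCO2B1, an organic anion transporter, of 6.55 ± 1.30 (SE), and HNRNPLL, a splicing regulator, of 6.25 ± 0.89 (SE). LILRA6 (6.33 ± 0.66) and LILRB3 (5.82 ± 0.79) are leukocyte immunoglobulin-like receptors with near-identical sequence, so their separate levels are uncertain. The largest fall was that of IGLL1, a surrogate immunoglobulin light chain, with a log2 change of -6.80 ± 0.89 (SE), although its shRNA control libraries differed (925 and 166). PDYN, which encodes prodynorphin, changed by -4.40 ± 0.61 (SE) and TNFRSF19 by -3.10 ± 0.60 (SE). KCNJ11, DAB2IP, PHF24, MATN4, CAB39L and SAMD11 fell by log2 changes of -2.64 to -2.22.

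Of 41 interferon-stimulated genes measured, 12 rose, 0 fell and 29 were not called, and 31 were called adjusted over the list alone. The list was called upward by camera (adjusted p = 9.40e-27, and adjusted p = 0.295 with an estimated correlation), with a median log2 change of 2.07. Its members included IFIT5 (4.56 ± 0.71), SAMD9L (4.34 ± 0.69) and IFI16 (2.69 ± 0.44), all interferon-induced, the last a DNA sensor. Of 37 monocyte and macrophage differentiation genes 15 rose and 22 were not called, with 29 called adjusted over the list alone (camera adjusted p = 4.68e-23, and adjusted p = 0.218 with an estimated correlation). CD86, a costimulatory ligand, changed by 5.16 ± 0.68 (SE) and C5AR1, the complement C5a receptor, by 5.16 ± 0.71 (SE). The library IRF2BP2 shRNA 1 replicate 3 was far above the other knockdown libraries for CD86, and the library labelled IRF2BP2 shRNA 2 replicate 3 for C5AR1.

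Of 33 Toll-like receptor and inflammasome genes 6 rose and 27 were not called, with 12 called adjusted over the list alone (camera adjusted p = 3.25e-10, and adjusted p = 0.111 with an estimated correlation). They included MEFV (3.32 ± 0.50), which encodes pyrin, AIM2 (3.61 ± 0.66), a DNA-sensing inflammasome receptor, NLRC4 (2.85 ± 0.58) and TLR6 (2.87 ± 0.62). Of 22 cytokines and chemokines 3 rose and 19 were not called, with 10 called adjusted over the list alone (camera adjusted p = 7.60e-08, and adjusted p = 0.218 with an estimated correlation). These were the chemokines CXCL8 (4.71 ± 0.55) and CCL2 (3.70 ± 0.52) and the interleukin-1 receptor antagonist IL1RN (2.58 ± 0.44). Of 46 NF-kB target genes 3 rose, namely IL4I1 (2.14 ± 0.40), PTGS2 (2.96 ± 0.66) and KLF6 (1.69 ± 0.38), and 43 were not called, with 10 called adjusted over the list alone (camera adjusted p = 1.21e-05, and adjusted p = 0.313 with an estimated correlation). Of 25 AP-1 and immediate early genes 6 rose and 19 were not called, with 7 called adjusted over the list alone (camera adjusted p = 4.76e-07, and adjusted p = 0.313 with an estimated correlation). FOSL2 (3.17 ± 0.50) and FOS (3.09 ± 0.64), AP-1 subunits that can dimerize with JUN proteins, were the 2 members of the list of targets and partners that rose. In that list 17 of 19 genes were not called and 3 were called adjusted over the list alone (camera adjusted p = 0.00484, and adjusted p = 0.320 with an estimated correlation). KLF2 (2.64 ± 0.39) and BTG2 (1.49 ± 0.28) were further AP-1 and immediate early genes that rose.

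Lysosome genes (29 measured, camera adjusted p = 1.45e-06, and adjusted p = 0.320 with an estimated correlation), MHC class I genes (15, adjusted p = 0.000287, and adjusted p = 0.320 with an estimated correlation) and unfolded protein response genes (25, adjusted p = 0.0122, and adjusted p = 0.501 with an estimated correlation) were called upward with 0 members called, also when adjusted over the list alone. Apoptosis genes were called upward (37 measured, 1 rose, 6 adjusted over the list alone, camera adjusted p = 0.0103, and adjusted p = 0.313 with an estimated correlation). MHC class II genes were called upward (5 measured, 1 rose, 2 adjusted over the list alone, camera adjusted p = 0.0418, and adjusted p = 0.410 with an estimated correlation), the member being HLA-DRB5 (1.64 ± 0.36), whose reads are hard to part from those of HLA-DRB1. Another 5 lists were called downward with no member called: cytosolic ribosomal proteins (48 measured, camera adjusted p = 4.10e-07, and adjusted p = 0.313 with an estimated correlation), integrated stress response genes (35, adjusted p = 0.000130, and adjusted p = 0.320 with an estimated correlation), MYC and ribosome biogenesis genes (42, adjusted p = 0.00103, and adjusted p = 0.511 with an estimated correlation), leukaemia stem and progenitor genes (27, adjusted p = 0.0141, and adjusted p = 0.313 with an estimated correlation) and proliferation genes (53, adjusted p = 0.0334, and adjusted p = 0.691 with an estimated correlation). Adjusted over the list alone, 1 integrated stress response gene was called and 0 in the other lists that went down. The call of proliferation genes ended under quantile normalization (adjusted p = 0.0533) and without the 3 libraries far from the median (0.579), settings added after the data were seen, and without shRNA control replicate 1 (0.0659), IRF2BP2 shRNA 1 replicate 3 (0.102) or shRNA 2 replicate 3 (0.201). That of MHC class II genes ended without those 3 libraries (0.0511), shRNA control replicate 3 (0.129), or IRF2BP2 shRNA 2 replicate 2 (0.0722) or replicate 3 (0.0614). Without shRNA control replicate 3 the calls of targets and partners (0.0625), apoptosis genes (0.0649) and unfolded protein response genes (0.0723) ended too. With the replicate number as a block those of MHC class II and unfolded protein response genes ended (camera adjusted p = 0.0688 for both). Oxidative phosphorylation genes, not called as deposited (0.0926), were called downward with equal totals (0.0425, and adjusted p = 0.569 with an estimated correlation). In all, 17 of 29 lists were called, 12 upward and 5 downward, 0 with an estimated correlation and 3 by fry. Those 3 were Toll-like receptor and inflammasome genes (fry adjusted p = 0.0106), cytokines and chemokines (0.0337), and monocyte and macrophage differentiation genes (0.0390). Interferon-stimulated genes were not called by fry (adjusted p = 0.0837).

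The other 12 lists were not called in the knockdown (camera adjusted p from 0.0926 to 0.934), among them the markers of lymphoid, erythroid, epithelial and stromal cells. Of the stromal markers FN1, which encodes fibronectin, rose (2.42 ± 0.55). CDKN1A (3.17 ± 0.51), which encodes the cell cycle inhibitor p21, TIGAR (1.86 ± 0.41) and BTG2 rose among 27 p53 target genes, of which 24 were not called. In the list of 14 primary granule genes CAMP (4.09 ± 0.91) rose and 13 were not called, with 7 called adjusted over the list alone. CAMP encodes cathelicidin, a protein of specific granules, so its rise is not that of a primary granule gene. The median and the test differed in sign for primary granule genes, p53 targets, and erythroid and megakaryocyte markers.

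**Figure D3:**
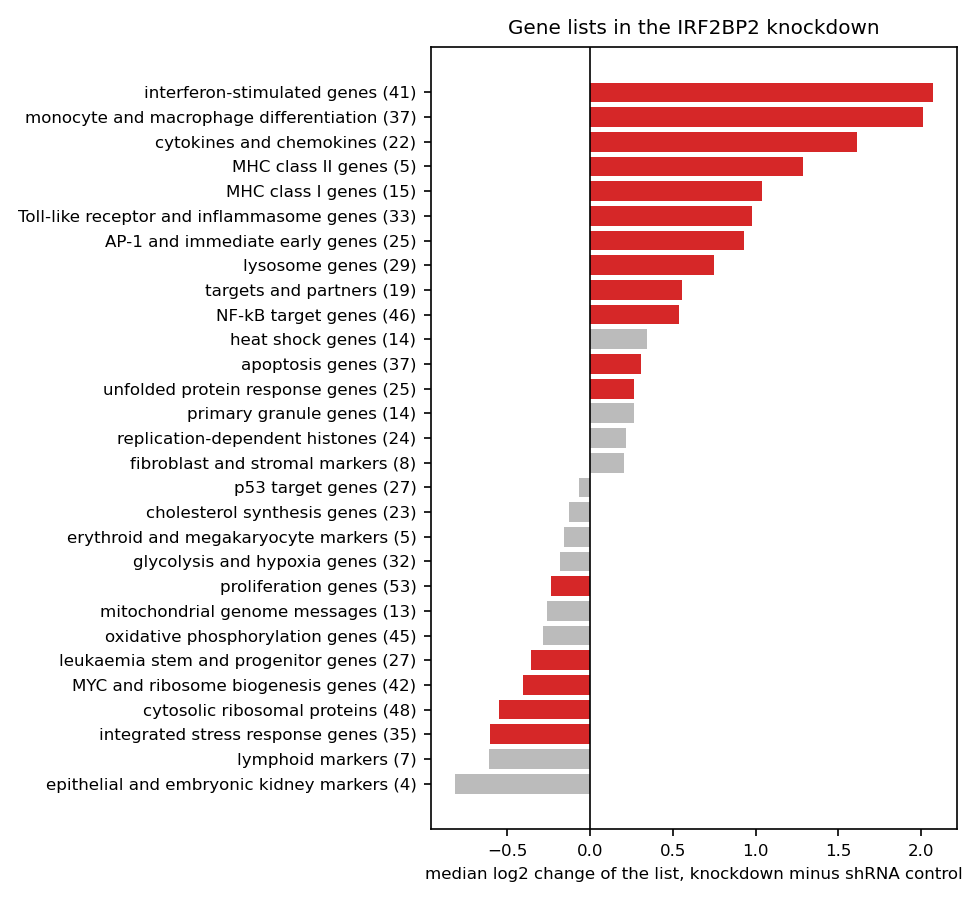
Median log2 change of each of 29 gene lists in the IRF2BP2 knockdown, with the number of measured genes in brackets. Red bars are lists with a camera adjusted p under 0.05 and gray bars the others. The largest medians were 2.07 for interferon-stimulated genes and 2.01 for monocyte and macrophage differentiation genes.

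Of 12738 genes tested, limma called 228 in the knockdown, of which 196 were higher and 32 lower, and the authors' deposited table called 225 of these in the same direction among its 2279 (1386 higher and 893 lower). The count was 11 without shRNA control replicate 1, 62 without shRNA control replicate 3, 134 without IRF2BP2 shRNA 1 replicate 2 and 609 without IRF2BP2 shRNA 1 replicate 3. It was 124 with edgeR (89 higher and 35 lower), 682 with DESeq2 (528 and 154), 1514 with array weights (952 and 562) and 1251 without the 3 libraries far from the median (784 and 467), a set chosen after the data were seen. Among the named genes, GPR34, LILRA6, SIGLEC9 and CXCL8 passed the test without shRNA control replicate 1.

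The hairpins were compared with each other to see whether they differed in effect. Limma called 0 of 12738 genes between shRNA 2 and shRNA 1, with 917 genes at an unadjusted p under 0.05. The risen genes, which were picked over both hairpins together, had a median log2 change of 3.12 in shRNA 1 and 3.07 in shRNA 2. Without IRF2BP2 shRNA 1 replicate 3, 1 gene was called.

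The ATF7 knockout was compared with the knockout control to find messages that depend on ATF7. NDUFB4, a subunit of respiratory complex I, fell from 11518 ± 1078 (SD, n = 2) to 1472 ± 593 normalized counts (SD, n = 4), a log2 change of -3.07 ± 0.36 (SE) with a limma adjusted p of 0.0104. UQCR10, a subunit of complex III, fell from 3622 ± 1451 to 606 ± 259, a log2 change of -2.64 ± 0.46 (SE, adjusted p = 0.0384). The list of oxidative phosphorylation genes, which holds neither, was not called (45 measured, 0 called, median 0.24, camera adjusted p = 0.655). The ribosomal protein genes RPL19 (-2.76 ± 0.39) and RPS20 (-2.66 ± 0.47) fell, but both have many processed pseudogenes, so their levels are uncertain where reads were split. UROD, an enzyme of heme synthesis, changed by -2.53 ± 0.33 (SE), the histone variant gene H2AZ1 by -2.52 ± 0.31 (SE), and ALKBH2, a DNA repair enzyme, by -2.47 ± 0.25 (SE). TRAPPC4, HYPK and VPS25 changed by -2.45 to -2.35. In wild type and shRNA control NDUFB4 stood at 3417, 8353 and 6811, above each ATF7 knockout library (756 to 2097), as was the case for RPL19, RPS20, ALKBH2 and VPS25. UROD stood at 849, 1590 and 913 and H2AZ1 at 4463, 7972 and 4914, which overlapped their ATF7 knockout libraries (599 to 1046 and 3104 to 5488), as was the case for UQCR10, TRAPPC4 and HYPK. The IRF2BP2 knockdown libraries, which hold no knockout, are not part of these ranges. Over the 89 genes that fell in either knockout their medians ran from -0.31 to 0.76 on the log2 scale against wild type and shRNA control. Of the 10 genes named here as fallen the authors' deposited table called NDUFB4, RPS20 and ALKBH2 and not the others. UROD stood there at -1.15 ± 0.43 (SE, DESeq2 adjusted p = 0.281) and H2AZ1 at -1.29 ± 0.38 (SE, DESeq2 adjusted p = 0.0973). The deposited change of NDUFB4, called by both, was -1.98 ± 0.38 (SE) against -3.07 here, so the sizes are not comparable. Limma called 0 genes higher, with 233 higher at an unadjusted p under 0.05, against 0 higher by edgeR and 12 by DESeq2.

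Of 48 cytosolic ribosomal protein genes 2 fell and 46 were not called, with 6 called adjusted over the list alone, and the list was not called (camera adjusted p = 0.438, median 0.08, mean -0.23). AP-1 and immediate early genes were called upward as a list in the ATF7 knockout (25 measured, 0 called, 0 adjusted over the list alone, camera adjusted p = 9.59e-05, and adjusted p = 0.938 with an estimated correlation), with JUNB at 1.05 ± 0.43 (SE, adjusted p = 0.611). NF-kB target genes were called upward (45 measured, 0 called, 0 adjusted over the list alone, camera adjusted p = 0.0274, and adjusted p = 0.938 with an estimated correlation). Lists called numbered 7 without knockout control replicate 1, 9 and 4 without ATF7 knockout clone 1 replicate 2 and clone 2 replicate 2, and 1 without knockout control replicate 2, JDP2 knockout clone 1 replicate 1 or ATF7 knockout clone 1 replicate 1. Without knockout control replicate 2 neither AP-1 and immediate early genes (adjusted p = 0.446) nor NF-kB target genes (0.694) were called, and without the other 2 of these the call of NF-kB target genes ended (0.0504 and 0.0902). The other 27 lists were not called (adjusted p from 0.0514 to 0.961), interferon-stimulated genes among them (39 measured, 1 adjusted over the list alone, adjusted p = 0.106). After quantile normalization interferon-stimulated genes were called downward (0.0297), and targets and partners were called upward with it (0.0300) and with equal totals (0.0314). With an estimated correlation these calls ended (adjusted p = 0.952 for interferon-stimulated genes, and adjusted p = 0.835 and 0.843 for targets and partners). Of 6 lists whose median, mean and test differed in sign, 0 were called.

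Limma called 33 of 13208 genes in the ATF7 knockout, all lower. Over the 89 genes that fell in either knockout, wild type and shRNA control had a median log2 difference of -0.90 from the knockout control, so these control libraries also lay below it. The count was 0 without knockout control replicate 1 (1132 at an unadjusted p under 0.05) or replicate 2 (566), 98 without JDP2 knockout clone 1 replicate 2, 14 and 11 without JDP2 knockout clone 2 replicates 1 and 2, 2 and 8 without ATF7 knockout clone 1 replicates 1 and 2, and 10 without ATF7 knockout clone 2 replicate 1. It was 33 with edgeR and 223 with DESeq2, and with wild type added to the control it was 0 (877 at an unadjusted p under 0.05). The authors' deposited table called 40 genes, of which 5 were among the 33. Which controls the authors used was checked for the knockdown only.

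The JDP2 knockout was compared with the same control libraries to find messages that depend on JDP2. NBDY, which encodes a microprotein of processing bodies, fell from 182 ± 20.4 (SD, n = 2) to 0.527 ± 1.05 normalized counts (SD, n = 4), a log2 change of -7.10 ± 0.90 (SE) with a limma adjusted p of 0.00724, and had 0 reads in 3 of 4 libraries. NDUFB4 changed by -3.72 ± 0.36 (SE, adjusted p = 0.00254). The chemokine CCL5 fell from 5002 ± 322 to 690.1 ± 96.1, a log2 change of -2.86 ± 0.47 (SE, adjusted p = 0.0188), and the interferon-induced antiviral gene IFITM2 from 7737 ± 1390.5 to 1322 ± 199, a log2 change of -2.55 ± 0.39 (SE, adjusted p = 0.0151). ACTL8, an actin-like gene, rose from 1958 ± 342 to 6621 ± 1508, a log2 change of 1.74 ± 0.26 (SE, adjusted p = 0.0143), and FOXO6, a forkhead transcription factor, changed by 1.43 ± 0.29 (SE, adjusted p = 0.0496).

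Further falls in the JDP2 knockout were those of SF3B5 (-3.41 ± 0.59), a splicing factor subunit, UQCR10 (-2.76 ± 0.46), ATPAF1 (-2.73 ± 0.54), an assembly factor of ATP synthase, and TUBB (-2.61 ± 0.34), a beta-tubulin whose reads can be shared with related genes. RPL19 (-3.05 ± 0.39), RPS20 (-2.86 ± 0.47) and RPL10 (-1.95 ± 0.38) fell among 48 cytosolic ribosomal protein genes, with the same doubt about pseudogenes. Of that list 45 genes were not called and 4 were called adjusted over the list alone (camera adjusted p = 0.991, median 0.17, mean -0.13). With wild type and shRNA control in place of the knockout control, a set chosen after the data were seen, 11 of the genes called in the JDP2 knockout stayed called. RPL19, RPS20, RPL10, SF3B5, UQCR10, TUBB and IFITM2 were not among them, so their calls rest on the knockout control libraries. They were still lower in that setting, which called 20 genes in all. CCL5 was the 1 of 15 cytokines and chemokines called and IFITM2 the 1 of 39 interferon-stimulated genes called, each also adjusted over the list alone, and neither list was called (camera adjusted p = 0.991 and 0.114). AP-1 and immediate early genes (25 measured, 0 called, 0 adjusted over the list alone) and unfolded protein response genes (25 measured, 0 called, 1 adjusted over the list alone) were called upward, each with a camera adjusted p of 0.0423, and adjusted p = 0.959 with an estimated correlation. The unfolded protein response call ended under quantile normalization (adjusted p = 0.0871), and scaling to equal totals shifted the median of all genes by -0.22. After quantile normalization NF-kB target genes were called upward (0.0492) and lysosome genes downward (0.0487), and with equal totals primary granule genes (0.0411) and replication-dependent histones (0.0332) were called upward. With an estimated correlation these calls ended (adjusted p = 0.953 after quantile normalization and adjusted p = 0.945 with equal totals, for each of the lists). Lists called numbered 4 without knockout control replicate 1, 9 without JDP2 knockout clone 2 replicate 2, and 0 without ATF7 knockout clone 1 replicate 1 (adjusted p = 0.0502 for both) or replicates 1 and 2 of ATF7 knockout clone 2 (0.0566 and 0.0515 for both). Both calls also ended without knockout control replicate 2 (0.822 for AP-1 and immediate early genes and 0.207 for unfolded protein response genes), JDP2 knockout clone 1 replicate 1 (0.115 for both) or JDP2 knockout clone 2 replicate 1 (0.0609 and 0.106), where 2 other lists were called, and that of AP-1 and immediate early genes ended with the GC trend removed (0.143). The other 27 lists were not called (adjusted p from 0.0630 to 0.993), and of 6 lists whose median, mean and test differed in sign 0 were called.

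**Figure D4:**
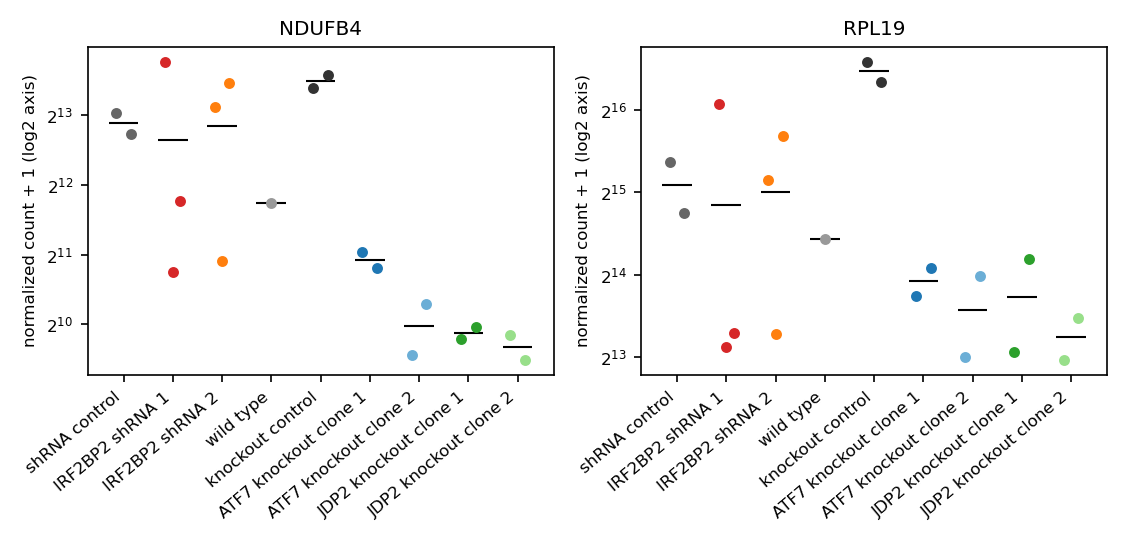
Normalized counts plus 1, on a log2 axis, of NDUFB4 and RPL19 in each library, by group. Points are libraries and horizontal bars are group means of the counts. NDUFB4 stood at 10756 and 12281 in the knockout control libraries, at 3417 in wild type, at 8353 and 6811 in shRNA control and between 716 and 2097 in the knockout libraries, and RPL19 ranged from 8892 to 69151 within shRNA 1.

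Limma called 89 of 13208 genes in the JDP2 knockout, of which 2 were higher and 87 lower. The count was 0 without knockout control replicate 1 (2211 at an unadjusted p under 0.05) or replicate 2 (762), 12 and 20 without JDP2 knockout clone 2 replicates 1 and 2, 56 without JDP2 knockout clone 1 replicate 1, 56 and 54 without ATF7 knockout clone 1 replicates 1 and 2, and 49 without ATF7 knockout clone 2 replicate 2. It was 122 with edgeR (2 higher and 120 lower) and 526 with DESeq2 (151 and 375), with wild type added to the control it was 14, with wild type and shRNA control added, a set chosen after the data were seen, it was 919 (501 and 418), and the authors' deposited table called 1489 genes (931 and 558), of which 74 were among the 89 in the same direction.

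The knockouts were compared with each other because ATF7 and JDP2 can act as partners. Limma called 0 of 13208 genes between them, with 289 at an unadjusted p under 0.05. Across 13208 genes, which are not independent replicates, the log2 changes of the ATF7 and JDP2 knockouts had a Spearman rho of 0.814 and a Pearson r of 0.782. Unchanged groups simulated against the same 2 control libraries gave a mean rho of 0.623 and a mean r of 0.667. The covariance was 0.347, against 0.269 simulated, a difference of 0.0782. Both knockouts shared 31 called falls, where independent lists of 33 and 87 genes would share 0.217, and the simulated groups shared at most 1. The simulated groups were unchanged, with noise independent between genes. Neither number therefore tells how many of 33 and 87 calls would coincide through the shared control libraries alone. The shared genes with the largest changes were NDUFB4, RPL19, RPS20, UQCR10 and UROD. With the ATF7 knockout against knockout control replicate 1 and the JDP2 knockout against replicate 2, a setting chosen after the data were seen, the rho was 0.186 and the r 0.115, and with these libraries exchanged 0.437 and 0.387. All 31 shared genes, which were picked against both control libraries, were lower in both knockouts either way, but limma then called 0 genes in either (569 and 2219 at an unadjusted p under 0.05, and 1136 and 760 when exchanged), with a lone control library assumed to vary as the other groups do.

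The clones of each knockout were compared to see how far single-cell clones of 1 target differed. In ATF7 clone 2, CERS1, a ceramide synthase, was higher than in clone 1 (833 ± 166 against 10.8 ± 6.16 normalized counts, SD, n = 2 each), a log2 difference of 6.23 ± 0.57 (SE) with a limma adjusted p of 0.00112. LRP3, DNAJC15, GAL and EPS8L1 were higher in clone 2 by log2 differences of 5.76 to 6.16. RENBP was lower (-7.37 ± 0.58), as were ITGAD, CD74, the MHC class II invariant chain, CAMP and POU2F2, by -7.03 to -4.13. Limma called 40 genes between the ATF7 clones, 20 higher and 20 lower in clone 2, and 17 to 198 when any 1 library was left out, with the count moved by over 1.5 times by either knockout control library (18 each), by JDP2 knockout clone 1 replicates 1 and 2 (193 and 198), by JDP2 knockout clone 2 replicates 1 and 2 (25 and 26) and by ATF7 knockout clone 1 replicates 1 and 2 (17 each).

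In JDP2 clone 2, POU4F1, a POU-domain transcription factor, stood at 0.640 ± 0.905 against 2121 ± 154 normalized counts in clone 1, a log2 difference of -10.46 ± 0.41 (SE) with a limma adjusted p of 1.26e-06. LRP3, HDHD3, EPS8L1 and KCNG1 were lower by -7.65 to -7.41, and PSTPIP2, PTPRF, CSTPP1 and TMEM132B were higher by 2.66 to 5.89. Limma called 18 genes, 4 higher and 14 lower in clone 2, and 266 without JDP2 knockout clone 1 replicate 1.

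Whether the knockdown and the knockouts moved the same genes was tested last, since the title sets IRF2BP2 against the ATF7 and JDP2 pair. GPR34 differed between the knockdown effect and the ATF7 knockout effect by 6.25 ± 0.95 (SE, limma adjusted p = 0.0242), OAS1 by 5.67 ± 0.92 (SE, adjusted p = 0.0242), CCR1 by 3.82 ± 0.68 (SE, adjusted p = 0.0263) and TERT by -3.08 ± 0.62 (SE, adjusted p = 0.0379). Against the JDP2 knockout effect they differed by 6.31 ± 0.95 (GPR34), 5.82 ± 0.92 (OAS1), 4.04 ± 0.68 (CCR1) and -3.69 ± 0.62 (TERT). GPR34, OAS1, CCR1 and TERT were picked for their called change in the knockdown, and the contrasts use the same knockdown and shRNA control libraries. Their tests here therefore largely restate that change and do not show an opposite change in the knockouts. No gene was called in both the knockdown and a knockout, where independent lists would share 0.443 genes risen in the knockdown and fallen in the ATF7 knockout, and 1.17 for the JDP2 knockout. Of the 168 genes risen in the knockdown and also tested in the knockouts, 59 had the opposite sign in the ATF7 knockout (median log2 change 0.23) and 89 in the JDP2 knockout (median -0.04). Across 12505 genes the log2 changes of the knockdown had a rho of -0.0378 with the ATF7 knockout (r = 0.0345) and of -0.175 with the JDP2 knockout (r = -0.120). The rho with the ATF7 knockout was -0.153 without knockout control replicate 1 and 0.108 without knockout control replicate 2, and that with the JDP2 knockout was -0.241 and -0.0586.

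The effect differed in 44 of 13057 genes for the ATF7 knockout (36 higher in the knockdown and 8 lower) and in 230 for the JDP2 knockout (191 and 39), by limma interaction contrasts. For ATF7 the count was 0 without any 1 of the 4 control libraries (893 to 1535 at an unadjusted p under 0.05), and moved by over 1.5 times without any 1 ATF7 knockout library (15, 5, 27 and 14), JDP2 knockout clone 1 replicate 2 (96), JDP2 knockout clone 2 replicate 1 (26) or IRF2BP2 shRNA 1 replicate 3 (91). For JDP2 it was 1 and 35 without shRNA control replicates 1 and 3, 14 and 3 without knockout control replicates 1 and 2, 91 without JDP2 knockout clone 2 replicate 2, and 430 without IRF2BP2 shRNA 1 replicate 3.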

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

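The limma comparisons between clones, hairpins, knockouts and arms and the replicate block were planned, and the splits of the libraries and the tests of explanations in this part were chosen after the result was seen. A library was singled out where its gap to the nearest other library of its group was large against the range of the group (Dixon's criterion). Such a library was found in 25 of 87 groups of values tested, where chance gives about 1 in 20 for normally distributed values. Gene levels were compared as normalized counts, not on the log2 scale, and a skew to high values raises that share by itself. Values of 1 library are also not independent of each other, so the excess over 1 in 20 is not a test.

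In the library labelled IRF2BP2 shRNA 2 replicate 3, normalized counts lay far above those of the other knockdown libraries for FOSL2 (51147), FOS (6837), SLCO2B1 (4384), LILRA6 (3582), SIGLEC9 (226), LILRB3 (4437), IL1RN (2083), KLF2 (389.6), C5AR1 (26187), CAMP (12191) and CDKN1A (9778). In IRF2BP2 shRNA 1 replicate 3 this held for ATF7 (1337), AQP9 (741), CXCL8 (2037), CCL2 (4671), SAMD9L (3277), IFI16 (12721), AIM2 (333), NLRC4 (706) and CD86 (2006). IRF2BP2 shRNA 1 replicate 2 had the most reads of the knockdown group (46.5 M, nearest 37.1 M). In JDP2 knockout clone 1 replicate 2, 34.6 percent of genes lay more than 2-fold from the median of all libraries, against 5.14 percent in the nearest library of that knockout, ATF7 stood at 168 and RPS20 at 13128. NBDY stood at 2.11 in JDP2 knockout clone 1 replicate 1 and at 0 in the other JDP2 knockout libraries.

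The 196 genes that rose in the IRF2BP2 knockdown had a median log2 change of 3.10. Without the libraries far from the median of all libraries it was 2.78, and with each library's GC trend removed it was 3.15, so neither the far libraries nor GC content accounts for the rise. Over 347 genes called higher in the knockdown than in wild type and knockout control (median 2.16, with 169 of the 196 among them), shRNA control lay at 0.030 against the same controls (its libraries at -0.16 and 0.20), although that choice of genes favors a raised value, which argues against an effect of carrying any hairpin vector. Over 53 genes called higher in shRNA 1 alone, a choice that favors shRNA 1, shRNA 2, whose IRF2BP2 message was not lowered on average, lay at 3.51 against wild type and knockout control (its libraries at 2.70 to 4.73) and shRNA 1 at 3.31, which argues against the message level of a library as what set the size of the rise. A loss of IRF2BP2 protein that the message does not show, and an effect shared by both hairpins but not by the control hairpin, may each underlie it, and neither was tested.

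The 89 genes that fell in the ATF7 or JDP2 knockouts had a median log2 change of -1.67 against the knockout control, and of -1.49 with the GC trend removed, which argues against GC content as the cause. Wild type and shRNA control lay at -0.90 against the knockout control over these genes, so the 2 knockout control libraries standing apart may account for a large part, although genes picked for being high in those libraries tend to lie above other controls for that reason alone. Against wild type and shRNA control the knockouts had a median of -0.74, with 85 of the 89 genes lower. The 89 genes were picked for being low in these same knockout libraries, which favors lower values against any controls. Loss of ATF7 or JDP2 is neither shown nor excluded by these values and stays open. These genes also moved in libraries without a knockout, with medians of 0.76 in IRF2BP2 shRNA 1 replicate 1, 0.69 in shRNA 2 replicate 3 and -0.31 in shRNA 1 replicate 2 against wild type and shRNA control, and their median length was 1134 against 1819 for genes of like level. They had a median range of 1.36 on the log2 scale within the 3 libraries of shRNA 1, which hold no knockout, against 1.00 for genes of like level, and whether such variation between libraries contributes cannot be told apart from a knockout effect because a group of controls with more libraries would be needed.

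Between the clones of 1 knockout, 40 genes differed for ATF7 and 18 for JDP2 by limma. Log2 differences of ATF7 clone 2 minus clone 1 were 6.23 for CERS1, 6.16 for LRP3, 6.11 for DNAJC15, 5.87 for GAL, 5.76 for EPS8L1, -7.37 for RENBP, -7.03 for ITGAD, -5.94 for CD74, -4.74 for CAMP and -4.13 for POU2F2. Those of JDP2 clone 2 minus clone 1 were 5.89 for PSTPIP2, 5.08 for PTPRF, 4.56 for CSTPP1, 2.66 for TMEM132B, -10.46 for POU4F1, -7.65 for LRP3, -7.63 for HDHD3, -7.60 for EPS8L1 and -7.41 for KCNG1. Genes over 10-fold below the lowest wild-type or shRNA control library in both libraries of a clone numbered 22, 4, 7 and 28 of 10706 in ATF7 clones 1 and 2 and JDP2 clones 1 and 2. ATF7 clone 1 and JDP2 clone 2 shared 12 of them, where independent lists would share 0.0575. The ATF7 clones shared 1 (0.00822 if independent) and the JDP2 clones 3 (0.0183 if independent). The lists of ATF7 clone 2 and JDP2 clone 1 held only 4 and 7 genes, so clones of 1 knockout could not share 12. These counts therefore do not tell whether loss of the targeted gene contributes. For 11 of the 12 genes shared by ATF7 clone 1 and JDP2 clone 2, the knockout control mean was also below the lowest wild-type or shRNA control library. This held for 24.1 percent of the genes considered. ATF7 clone 1 and JDP2 clone 2 still differed in 13 genes, which argues against 1 clone under 2 labels. Cloning from a common mixed population may give such shared losses, which was not tested beyond these values.

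The knockdown effect differed from the ATF7 knockout effect in 44 genes and from the JDP2 knockout effect in 230. Between the knockouts limma called 0 genes (289 at an unadjusted p under 0.05), and 35 of 35 splits of the 8 knockout libraries gave at least as many, as any split does beside a count of 0, so the splits do not tell whether chance can be excluded. The highest other split called 1282 genes and parted the replicate 1 from the replicate 2 libraries of all 4 clones, which points to a structure of the samples that follows the replicate number. Not every same-numbered pair of knockout-arm libraries deviated together from the group means, however (r from -0.531 to 0.566). With the replicate number as a block, limma called 0 genes between the knockouts (401 at an unadjusted p under 0.05). Between the hairpins limma called 0 genes (917 at an unadjusted p under 0.05), 10 of 10 splits gave at least as many, as any split does beside a count of 0, and the highest other gave 0, while 10 splits are too few for a share under 0.05.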

How the results depend on the processing

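Settings chosen after the data were seen were the removal of each library's GC trend, the exclusion of the libraries far from the median, wild type and shRNA control added to or used in place of the knockout control, each knockout against a different knockout control library, and other scalings of the gene lists, with a preset or an estimated correlation. The cause of the moves was not tested, except that a fit with fewer libraries has fewer degrees of freedom. Settings not named left a count within 1.5 times of its value in the report. The 2 libraries marked as low quality were not analysed here, so including them was not run.

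The knockdown count of 228 was 1514 with array weights, 898 with the GC trend removed (648 higher and 250 lower), 124 with edgeR (89 higher and 35 lower), 682 with DESeq2, 380 in 1 fit of both arms, 1561 with wild type and knockout control added to the control, 1251 without the far libraries and 2279 in the authors' table. The ATF7 knockout count of 33 was 19 with no filter, 223 with DESeq2, 107 with the clone as a random block, 0 in 1 fit of both arms (884 at an unadjusted p under 0.05), 56 with only this knockout and the control, and 98 without the far libraries. With wild type added to the control it was 0 (877 unadjusted), with wild type and shRNA control added 3, and with them in place of the knockout control 0 (791 unadjusted). The JDP2 knockout count of 89 was 53 with no filter, 185 with array weights, 526 with DESeq2 (151 higher and 375 lower), 265 with the clone as a random block, 38 with only this knockout and the control, and 1489 in the authors' table (931 higher and 558 lower). With wild type added to the control it was 14, with wild type and shRNA control added 919 (501 higher and 418 lower), and with them in place of the knockout control 20. The count of genes with a knockdown effect unlike the ATF7 knockout effect was 71 after quantile normalization.

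Leaving out 1 library at a time gave 11 to 609 genes for the knockdown, 0 to 98 for the ATF7 knockout, 0 to 125 for the JDP2 knockout, 0 each time between the knockouts (245 to 459 unadjusted), 0 to 1 between the hairpins, 17 to 198 between the ATF7 clones and 12 to 266 between the JDP2 clones. For the knockdown effect against the ATF7 and JDP2 knockout effects it gave 0 to 96 and 1 to 430. Lists called were 14 to 20 for the knockdown, 1 to 9 for the ATF7 knockout and 0 to 9 for the JDP2 knockout. The log2 change of IRF2BP2 was -0.60 to -0.31. That of ATF7 was 0.79 without knockout control replicate 2 and turned to -0.044 without replicate 1, and that of JDP2 was 0.42 without replicate 1 and turned to -0.14 without replicate 2.

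The rho of the knockdown with the ATF7 knockout was -0.202 for shRNA 1 with clone 1, 0.133 in the authors' tables, and -0.153 to 0.108 with 1 library left out. That with the JDP2 knockout was -0.0277 for shRNA 2 with clone 2, -0.0614 in the authors' tables, and -0.241 to -0.0586. Between the knockouts it was 0.664 and 0.715 for ATF7 clone 1 with JDP2 clones 1 and 2, 0.732 and 0.599 for ATF7 clone 2 with them, 0.875 for genes with a mean of at least 50, 0.186 with the ATF7 knockout against knockout control replicate 1 and the JDP2 knockout against replicate 2, 0.437 with these exchanged, and 0.723 to 0.875 with 1 library left out. With an estimated correlation 0 lists were called in each comparison, also with equal totals or after quantile normalization, and with fry 3 for the knockdown and 0 for each knockout. For the ATF7 knockout 4 lists were called with the GC trend removed and 4 after quantile normalization, and for the JDP2 knockout 4 with equal totals.

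Genes named because they were called, and called lists, kept their direction in each setting run for them, and the log2 changes of ATF7 and JDP2, which were not called, did not. Values of named genes that stayed past the threshold, against those that did not, numbered 968 and 175 for the knockdown, 209 and 91 for ATF7, 295 and 94 for JDP2, 120 and 20 between the ATF7 clones and 117 and 9 between the JDP2 clones, and for lists 210 and 79, 26 and 12, and 16 and 22.

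Same-numbered libraries had correlated deviations (r over 0.1) in 3 of 7 pairs of the knockdown arm (r from -0.307 to 0.367). In the knockout arm 10 of 20 pairs did (-0.531 to 0.566). In these arms 3 of 8 and 6 of 10 libraries correlated best with 1 of their own number. Each knockout-arm group held 2 libraries, whose deviations from the group mean are mirror images. Each r between replicate 1 libraries therefore recurs between the replicate 2 libraries, and the knockout-arm counts rest on fewer independent values. Because some pairs had a negative r, the numbers were not taken to pair the libraries. An effect that follows the replicate number in the knockout arm is not excluded by these counts. With the replicate number as a block the counts were 209 for the knockdown (172 of the 228 kept), 74 for the ATF7 knockout (33 kept), 161 for the JDP2 knockout (89 kept), 0 between the knockouts (401 unadjusted), 93 and 21 between the clones, and 301 (246 higher and 55 lower) and 680 (460 and 220) for the knockdown effect against the ATF7 and JDP2 knockout effects. Lists called with this block were 15, 3 and 4, and in the knockdown the calls of unfolded protein response and MHC class II genes ended (adjusted p = 0.0688 for both).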

Other observations

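The comparison with wild type and shRNA control and the tests on chromosome 19 in this part were chosen after the result was seen. In the JDP2 knockout, 11 genes passed the limma test in the same direction both against the knockout control and against wild type and shRNA control. Both tests used the same JDP2 knockout libraries, so they are not independent. NDUFB4, ERCC3 and MLLT10 were also called in the ATF7 knockout (limma adjusted p = 0.0104, 0.0289 and 0.0289), and the others were not. ATPAF1 averaged 38.9 in the ATF7 knockout and 33.1 in the JDP2 knockout, and the authors' table called ATPAF1 and CCL5 lower in the ATF7 knockout. Against wild type and shRNA control, NBDY had a log2 change of -5.09 ± 0.76 (SE, adjusted p = 0.0452), ATPAF1 of -3.19 ± 0.45, NDUFB4 of -2.73 ± 0.36 and CCL5 of -2.37 ± 0.41. BCL6, a transcriptional repressor, changed by -1.50 ± 0.24, MLLT10, a fusion partner of KMT2A in leukemia, by -1.29 ± 0.21, and ERCC3, a helicase of TFIIH, by -1.25 ± 0.20. These genes were chosen after their values were seen. DNAH1, RBM34 and PGPEP1 were lower by -1.52 to -1.28, and ACTL8 was higher by 1.71 ± 0.27.

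NBDY stood at 10.8 to 32.5 normalized counts in the ATF7 knockout libraries and at 31.9 to 67.7 in wild type and shRNA control, against 0 to 2.11 in the JDP2 knockout libraries. It was chosen by the rule for named genes, and its ATF7 knockout change did not pass the limma test (adjusted p = 0.268). Its mean there was 21.1, against 182 in the knockout control. The authors' deposited table called NBDY lower in the ATF7 knockout too (log2 change -1.62 ± 0.43, SE, DESeq2 adjusted p = 0.0437). Limma called 0 of 13208 genes between the knockouts, so the fall of NBDY is not shown to be particular to JDP2.

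Chromosome 19 held 19 of the 38 genes with little message in ATF7 clone 1 or JDP2 clone 2, 50 percent, against 7.81 percent of the genes considered (two-sided Fisher's exact p = 6.36e-12). Chromosome 19 was picked because it held the most of these genes, and neighboring genes are not independent. They include 6 zinc finger genes, ZNF331 among them, which stood at up to 2.17 in ATF7 clone 1 and at 0 in JDP2 clone 2. Over all chromosome 19 genes considered the median log2 change in these clones was -0.17, and in the other libraries of the knockout arm the same median ran from -0.62 to 0.66 (SD 0.45), so loss of a chromosome copy cannot be told apart because the spread between libraries is of the size that loss of 1 of several copies gives. That a state of single cells covers genes of this chromosome stays a hypothesis, for which the share on the chromosome was tested and neither the adjacency of the genes nor silencing was.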
